A study of Mus musculus with 24 samples.

How the data were processed

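The study measured total RNA from cerebellum, cortex, hippocampus and olfactory bulb of Cdr1as knockout and wild-type C57BL/6 mice, with 3 libraries per region and genotype. Per the labels' protocols, RNA was extracted with TRIzol, ribosomal RNA was removed by an RNase H method and libraries were made with a stranded total RNA kit. Per the submitters' processing notes, bcl2fastq 2.17.1.14, STAR 2.5.1b and HTSeq 0.6.1p1 were used with the mm9 build. The role and settings of each tool, and whether the counting used strand, are not given in the sources used here. The values deposited by the authors were raw whole-number counts of reads per gene, 1 table per library, with 37621 gene entries: 37620 Ensembl identifiers and a separate entry for Cdr1as named Cdr1asG.

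The 5 summary entries of each table were left out of library sizes and tests. Reads assigned to no feature came to 20.3% to 62.9% of all entries per library, reads without a unique alignment to 8.8% to 21.4% and ambiguous reads to 0.2% to 0.45%. Gene counts summed to 5.18 to 30.46 M per library, with a median of 16.9 M. Gene names came from GENCODE annotation of GRCm38, a later build than mm9, so that annotation gave names, 3′ UTR sequences and neighbour relations, and no coordinates are given. It matched 32897 of the Ensembl identifiers, which held 98.56% of the counts, and left 4723 unmatched. Every mitochondrially encoded gene had a count of 0 in every library. Of 659 entries in the gene lists, 5 had no matching gene.

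Knockout was tested against wild type in each region with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with TMM scaling and robust dispersion, on genes kept by filterByExpr at a minimum count of 10. For the mean over regions, log2 CPM (prior count 2) was averaged over the 4 regions for each genotype and replicate number, and 3 means were tested against 3 with limma 3.58.1 (trend, robust). Differences between regions were tested in edgeR as an interaction over all 24 libraries, and as each region against the mean of the others. Adjusted p-values are Benjamini-Hochberg values from edgeR or limma unless named otherwise, tests are two-sided, and 0.05 was the threshold. With no change at all, a share of about 0.05 of the genes tested would have an unadjusted p under 0.05. CPM per gene and region use library sizes scaled by TMM among the 6 libraries of that region. Values of the target locus and of single libraries use TMM over all 24 libraries. Zero-count floors use unscaled totals and 3 counts. These floors cover counting error only.

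A total of 35 gene lists (pathways, cell types, tissues, label checks) were written from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 measured members were tested with camera (limma), on voom values in each region and on the averaged log2 CPM for the mean over regions, at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. Members were also tested with p adjusted over the list alone. The lists of immediate early genes and described miR-7 targets are groups that the study's publication dwells on, so their counts are not independent evidence of direction. Named genes were (a) the 8 largest changes in each direction among genes past the threshold with mean log2 CPM of at least 1 and no overlap between genotypes, (b) up to 4 members of each list past the threshold adjusted over the list alone, or else up to 2 with the smallest p, (c) Cdr1 and its annotated neighbours, (d) Fos, Egr1, Arc, Junb, Nr4a3, Klf4, Irs2, Sik1 and Per1, (e) genes past the threshold in 3 or more regions, and (f) the 5 smallest p-values of the interaction test. The wording of (b) did not say over which genes to adjust, and the list alone was chosen later.

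Genes with a miR-7 site (GTCTTCC, or GTCTTCCA for the 8mer) or a miR-671-5p site (GGCTTCC, or GGCTTCCA) in the longest 3′ UTR of 19778 genes were compared with genes without one, matched in 10 bins of UTR length and 10 of expression. The shift was set among those of 79 shuffled sequences for miR-7 and 59 for miR-671-5p of the same base composition, as a permutation p. The number of expression bins was raised to the planned number, and the controls for 8mers alone were changed from shuffled 7mers to shuffled 8mers, after first values had been seen. Values from both sets of controls are given.

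The labels number replicates 1 to 3 in each group but do not say whether libraries with the same number share an animal or whether replicates are separate animals, so p-values measure the spread between these samples, which may be technical. Deviations from the group means correlated between same-numbered knockout and wild-type libraries at r = 0.14 to 0.59 in the cortex and 0.17 to 0.23 for the mean over regions, across genes, so a fit with the replicate number as a block is given beside those results where it changes a call. The pairing rests on these correlations, not on the labels. In the cortex, knockout 3 correlated more with wild type 1 (r = 0.32) than with wild type 3 (0.14). In the cerebellum, same-numbered libraries correlated weakly (0.06 to 0.11, against −0.08 to −0.01 between different numbers).

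The steps were tested on simulated data built from the real means and library sizes. For simulated 2-fold changes the tests recovered 38.8% in the cerebellum (15152 genes), 59.7% in the cortex (15561 genes), 74.6% in the hippocampus (15903 genes) and 53.7% in the olfactory bulb (15237 genes). The mean over regions recovered 88.1% and the interaction test 32.8% of changes made in the cortex alone (17395 genes each). Unchanged genes that were called numbered 5 in the cerebellum, 10 in the cortex, 14 in the hippocampus, 5 in the olfactory bulb and 14 in the mean. The interaction test called 7, beside 1, 22 and 41 genes recovered at 1.5-fold, 2-fold and 3-fold. The simulated libraries were drawn independently of each other and held many changed genes at once. That makes the adjusted threshold easier to pass, so recovery in the real libraries can be lower. Alternatives were DESeq2 1.42.0, other scaling factors, no filter and a stricter one (5 CPM in 3 libraries), removal of small RNA genes, a replicate block, 1 fit of all 24 libraries, sample quality weights, a prior count of 0.5, and each library left out in turn. Added after seeing the data were fits without 3 libraries of low complexity, fits with the share of reads in no feature as a covariate, lists without shared members, and 8mers against shuffled 7mers with and without matching. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.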

Results

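The data asked how gene expression differs in brain regions of mice that lack Cdr1as, a circular RNA of neurons that carries many binding sites for the microRNA miR-7 and is also targeted by miR-671. Each of the 4 regions (cerebellum, cortex, hippocampus, olfactory bulb) had 3 knockout and 3 wild-type libraries, 24 in all, with 5.18 to 30.46 M gene counts (M, mega). Region markers matched the labels: mean log2 CPM in the region of origin was at least 8.07 for cerebellum markers, and for cortex, hippocampus and olfactory bulb markers at least 6.68, 5.47 and 6.44, against at most 5.69, 3.04 and 3.33 in any library of another region. Xist lay at 0 to 2.05 CPM and the Y-linked Ddx3y at 37.8 to 88.6 CPM in every library. 3 libraries held under 8 M counts and under 17000 detected genes: cerebellum knockout 1 (6.5 M, 13741 genes), olfactory bulb wild type 1 (7.4 M, 16483 genes) and olfactory bulb knockout 2 (5.18 M, 14393 genes). The other 21 libraries held at least 9.9 M counts and 20024 to 22619 genes. No pair of replicates agreed within sampling noise.

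Cdr1as (entry Cdr1asG) was near absent in every knockout library. In wild type it was most abundant in the cerebellum at 4120 ± 273 CPM (SD, n = 3 here and below), followed by 976 ± 243 in the cortex, 865 ± 80.4 in the olfactory bulb and 510 ± 197 in the hippocampus. Knockout libraries held 0 to 13 counts each, or 0.235 ± 0.235, 0.355 ± 0.0503, 0.31 ± 0.203 and 0.567 ± 0.11 CPM in the same order of regions. The log2 fold change was −13.75 (SE 0.28, adjusted p = 1.23e-06, edgeR) in the cerebellum, −11.43 (SE 0.33, adjusted p = 5.73e-06) in the cortex, −11.29 (SE 0.21, adjusted p = 8.41e-09) in the olfactory bulb and −9.81 (SE 0.39, adjusted p = 6.01e-05) in the hippocampus. Without hippocampus wild type 1 the hippocampal value was −9.92 and missed the threshold (adjusted p = 0.127, the highest among the libraries left out). No other gene passed the threshold over all genes in 3 or more regions.

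Cdr1, the gene antisense to Cdr1as on the X chromosome, had a count of 0 in every knockout library. Because it lies at the altered locus, these counts cannot show that Cdr1 is regulated by Cdr1as. In the cerebellum, wild-type libraries held 124 Cdr1 counts (1.98 CPM pooled), so the knockout level was at least 26.5-fold lower, measured against a floor of 3 counts over 40.2 M (0.0746 CPM). Wild type 2 held 76 of these counts, and without it the ratio to the floor was 13.7 (48 counts, 1.02 CPM). The other regions held 7, 11 and 4 Cdr1 counts in wild type (cortex, hippocampus, olfactory bulb), only 2.72, 3.3 and 1.35 times the floor. C230004F18Rik, the noncoding gene within which Cdr1 lies on the opposite strand, was higher in knockout: 246 ± 31.3 against 104 ± 24.8 CPM in the cerebellum, 138 ± 96.7 against 56.6 ± 51.2 in the cortex, 216 ± 41 against 68.9 ± 15.8 in the hippocampus and 180 ± 35 against 93.6 ± 9.94 in the olfactory bulb. It passed in the cerebellum (log2 fold change 1.24, SE 0.19), hippocampus (1.65, SE 0.19), olfactory bulb (0.91, SE 0.15) and mean over regions (1.32, SE 0.27) with p adjusted over the list alone (the miR-7 and miR-671 network loci), at 5.58e-04, 3.10e-05, 4.19e-04 and 0.003. Over all genes the adjusted p-values were 0.867, 0.1, 0.313 and 0.682, and in the cortex (1.27, SE 0.70) it missed both, at 0.131 and 0.858. With the replicate block it passed over all genes in the cortex (1.42, SE 0.15) and in the mean over regions (1.32, SE 0.09), and in the hippocampus (1.66, SE 0.15, adjusted p = 0.0117), where the numbers do not pair the libraries. In edgeR on all 24 libraries, which takes regions as independent, it passed as well (1.27, SE 0.24, adjusted p = 0.0221), and with the share of reads in no feature as a covariate (1.20, SE 0.06, adjusted p = 5.84e-12). Cdr1as, antisense to Cdr1, lies on the same strand as C230004F18Rik, so no strand setting would separate their reads where they overlap. Cdr1 lies on the other strand, and because the strand setting of the counting is not known, its reads may not be separated either. These values are therefore uncertain.

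**Figure D1:**
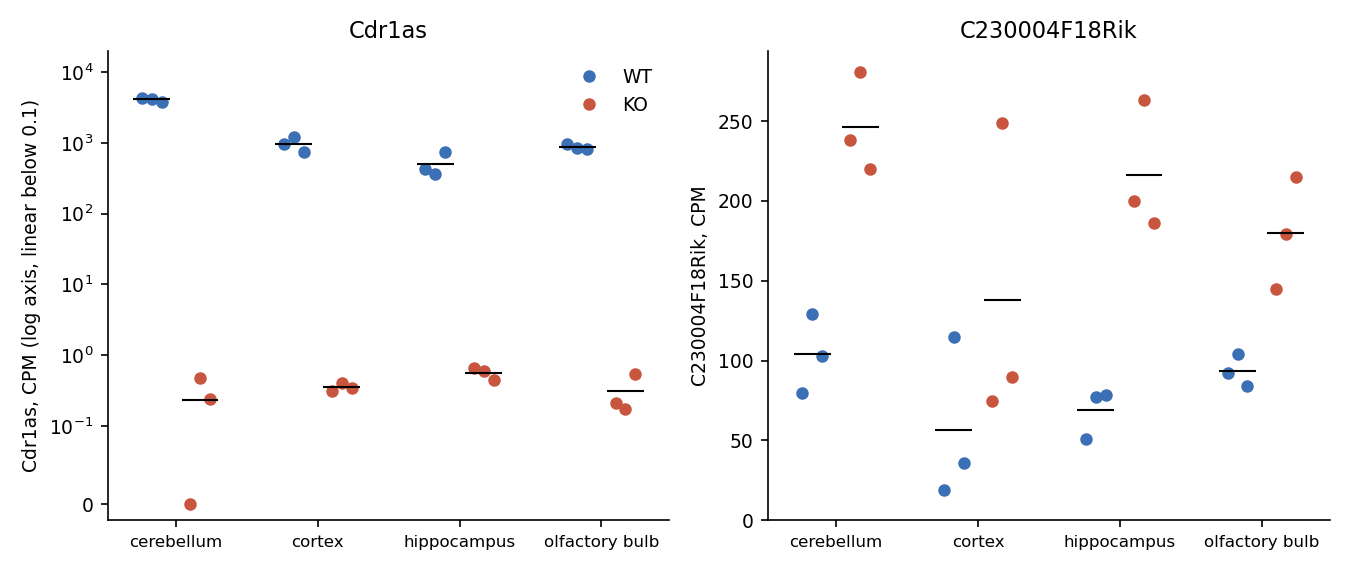
Left, Cdr1as in each library (CPM, log axis, linear below 0.1); right, C230004F18Rik (CPM, linear axis). Points are libraries and bars are means of 3: Cdr1as stands at 4120 CPM in wild-type cerebellum against 0.235 in knockout, and C230004F18Rik at 104 against 246.

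In the cerebellum, several immediate early genes, which neurons switch on rapidly after stimulation, were higher in knockout. The orphan nuclear receptor Nr4a3 stood at 85.9 ± 13 CPM against 22.1 ± 5.08 in wild type (log2 fold change 1.96, SE 0.19), and Fos, a subunit of the AP-1 transcription factor, at 56.7 ± 21.9 against 12 ± 4.86 (2.27, SE 0.38). Of 40 measured immediate early genes 32 were higher in knockout and 7 rose adjusted over the list alone: Fos, Nr4a3, Nr4a2 (1.65), Nr4a1 (1.57), Dusp1 (1.33), Fosl2 (1.22) and Sik1 (0.70), where Fosl2 was picked after its value was seen. Arc (−0.10, SE 0.19), Egr1 (0.01, SE 0.13), Junb (0.21, SE 0.35) and Klf4 (1.02, SE 0.45) did not pass. The list, which is not independent evidence of its direction, had a median of 0.46 (camera adjusted p = 1.11e-19, and adjusted p = 0.16 with an estimated correlation). Over its alternatives that p ran from 1.96e-25 to 0.171. The count of 7 became 1 without wild type 2 and 17 without knockout 1, the library of low complexity. Over all 15536 genes only Cdr1as passed. The next smallest adjusted p was 0.0813 (Nr4a3), 293 genes (1.9%) had an unadjusted p under 0.05, DESeq2 called 19, and 3 passed without knockout 1.

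Clock genes moved in both directions in the cerebellum. Of 22 measured members, 5 passed adjusted over the list alone: Dbp (−0.72, SE 0.13) and Ciart (−0.81, SE 0.24), both driven by the clock, and Per3 (−0.47, SE 0.14) fell, while Cry1 (0.55, SE 0.13) and Per1 (0.52, SE 0.15) rose. Per3 was picked after its value was seen. The list as a whole had a median of 0.05 (camera adjusted p = 0.69). Meningeal and fibroblast markers were higher in 14 of 17 (median 0.24, camera adjusted p = 4.81e-04, and adjusted p = 0.63 with an estimated correlation), with none past on its own, Aldh1a2 at 0.75 (SE 0.24) having the smallest p. Olfactory bulb markers were higher in 10 of 11 (median 0.35, adjusted p = 0.0451), of which Eomes, a transcription factor of unipolar brush cells here, rose (1.27, SE 0.17). Glucocorticoid response genes (median 0.12, adjusted p = 0.00722), blood cell markers (0.43, adjusted p = 0.04996), nuclear oxidative phosphorylation genes (0.05, adjusted p = 0.04996) and described miR-7 targets also passed as lists. With an estimated correlation the adjusted p was 0.63 for each but the miR-7 targets (0.16). Without Dusp1, also an immediate early gene, a step chosen after seeing the data, the glucocorticoid median was 0.03 (camera p = 0.0155, and 0.218 with an estimated correlation). The meningeal call ended without knockout 3 (0.17, adjusted p = 0.118), the olfactory marker call without knockout 1 (0.01, adjusted p = 0.491), wild type 2 (0.28) or wild type 3 (0.35), and the glucocorticoid call without wild type 2 (0.04) or knockout 3 (0.06). The blood call ended without wild type 1 (0.27), wild type 2 (0.48), knockout 1 (0.21) or knockout 3 (0.46), and the oxidative phosphorylation call without the same 4 (0.03, 0.02, 0.02 and 0.08). With the call kept, the median became 0.11 for meningeal markers without wild type 2 and 0.02 for glucocorticoid genes without knockout 2. It became 0.09 and 0.08 for oxidative phosphorylation genes without wild type 3 and knockout 2.

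In the cortex the rise of immediate early genes was broad. Arc, a cytoskeletal protein of active synapses, stood at 594 ± 92.5 CPM in knockout against 169 ± 65.4 (log2 fold change 1.81, SE 0.28), Fos at 73.9 ± 19.4 against 21.8 ± 5.54 (1.75, SE 0.24), and Egr2 (1.86, SE 0.26), Npas4 (1.62, SE 0.35) and Junb (1.58, SE 0.20) rose by similar amounts. Of 42 measured members 38 were higher and 29 rose adjusted over the list alone, among them Egr1 (1.01), Sik1 (1.02), Nr4a3 (0.99) and Klf4 (0.96). The clock genes Per1 (0.94, SE 0.11) and Bhlhe40 (0.74, SE 0.18) rose as well, adjusted over the list alone, while Irs2, an adaptor of the insulin receptor, did not (0.47, SE 0.27). The immediate early list is not independent evidence of its direction. Its median was 0.81 (camera adjusted p = 2.73e-34, and adjusted p = 0.348 with an estimated correlation), with p from 3.03e-40 to 0.348 over its alternatives. Over all 15777 genes only Cdr1as passed, with 890 (5.6%) at an unadjusted p under 0.05, where no change gives a share of 0.05. In this region same-numbered libraries correlated, most for number 2 (r = 0.59). Knockout 3 correlated more with wild type 1 (0.32) than with wild type 3 (0.14), so the pairing is not clean. With the number as a block 30 genes passed, 27 of them higher, including Junb, Nr4a1, Fos, Arc, Egr2, Npas4, Per1 and 16 immediate early genes in all. DESeq2 called 41 genes, 3 passed without wild type 2, and 62 passed with the share of reads in no feature as a covariate, an alternative chosen after seeing the data. That share was 20.3%, 56.2% and 34.9% in wild type 1 to 3 and 30.5%, 53.7% and 33.6% in knockout 1 to 3. It was highest in the libraries numbered 2 of both genotypes, so the replicate number and this share are not separated.

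Olfactory bulb and cerebellum markers were mostly lower in knockout cortex, while hippocampus markers were not shown to differ (9 of 14 higher, median 0.10, camera adjusted p = 0.574). Of 16 olfactory bulb markers 15 were lower and 7 fell adjusted over the list alone, with Eomes at 0.339 ± 0.226 CPM against 2.71 ± 0.953 in wild type (log2 fold change −2.98, SE 0.56), Shisa3 (−1.61, SE 0.35), Sp8 (−1.17, SE 0.30) and Th, the dopamine-synthesis enzyme (−1.15, SE 0.35). With the replicate block Eomes passed over all genes (−3.05, SE 0.49, adjusted p = 0.0303, edgeR). The list median was −0.52 (camera adjusted p = 1.42e-09, and adjusted p = 0.348 with an estimated correlation, the highest of its alternatives, which began at 2.68e-11). Pmch (0.334 ± 0.27 against 9 ± 7.72 CPM, −4.80) and Oxt (−2.60, SE 0.80), neuropeptides of the hypothalamus, and the cerebellum markers Zic1 (16.6 ± 3.11 against 33.1 ± 8.86 CPM) and Calb1 (−0.42, SE 0.12) fell adjusted over the list alone, and both lists passed (adjusted p = 0.00283 and 0.00303, and 0.556 and 0.348 with an estimated correlation). The 6 pituitary and hypothalamic markers had no common direction: 3 were higher, with medians of −4.05, −0.33 and 0.62 in the pairs numbered 1, 2 and 3. Their median of −0.73 became 0.07 without wild type 1, 0.02 without wild type 3, −1.59 without wild type 2, and −1.32, −1.56 and −3.35 without knockout 1, 2 and 3. GABA and glycine receptor subunits were lower in 16 of 18 (median −0.29, adjusted p = 1.89e-06, and 0.348 with an estimated correlation, from 1.83e-09 over its alternatives), with none past on its own and Gabrg1 (−0.72, SE 0.19) and Gabra4 (−0.42, SE 0.13) having the smallest p. Without wild type 1 the GABA and glycine receptor median was −0.19. Without knockout 2 the olfactory bulb marker median was −0.81. The cerebellum marker median of −0.19 was −0.33, −0.31 and −0.30 without wild type 2, wild type 3 and knockout 2.

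A further 7 lists passed camera in the cortex. Cell cycle and neurogenesis genes (median −0.17, adjusted p = 0.0123), inhibitory neuron (−0.09, adjusted p = 0.0307), oligodendrocyte (−0.13, adjusted p = 0.0149), oligodendrocyte precursor (−0.07, adjusted p = 0.0426) and striatum and thalamus markers (−0.21, adjusted p = 0.00303) were lower. So were the miR-7 and miR-671 network loci (−0.22, adjusted p = 0.0467), of which Cdr1as alone fell. That list includes Cdr1as, the gene knocked out, so its call cannot show that the other loci were lower. Cytosolic ribosomal protein genes were higher (0.11, adjusted p = 0.0191). With an estimated correlation their adjusted p was 0.348 to 0.881. The block ended the call of the network loci (adjusted p = 0.246) and brought glucocorticoid response and nuclear oxidative phosphorylation genes past the threshold. Except for cell cycle genes, whose call ended with the stricter filter (−0.17, adjusted p = 0.163), each of these 7 calls ended when some single library was left out. Medians were then −0.03, 0.12 and 0.05 for ribosomal genes (without wild type 2, knockout 1 and knockout 3), and 0.03 and −0.06 for oligodendrocyte markers (wild type 3, knockout 3). They were −0.14 in each case for striatum and thalamus (wild type 3, knockout 3) and −0.16, −0.19 and −0.22 for network loci (wild type 2, knockout 1, knockout 3). They were 0.00, −0.09 and −0.09 for inhibitory neuron markers (wild type 1, wild type 3, knockout 2) and −0.02, −0.11, −0.09 and −0.12 for precursor markers (wild type 1, wild type 3, knockout 2, knockout 3). With the call kept, medians were 0.25, 0.21 and 0.20 for ribosomal genes (without wild type 1, wild type 3, knockout 2) and −0.41 and −0.36 for striatum and thalamus (wild type 1, knockout 2). They were −0.27 for cell cycle genes (wild type 1), −0.17, −0.14 and −0.01 for inhibitory neuron markers (wild type 2, knockout 1, knockout 3) and −0.20 for precursor markers (wild type 2).

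In the hippocampus 35 of 42 immediate early genes were higher in knockout and 15 rose adjusted over the list alone. Egr2, a zinc-finger transcription factor, stood at 10.7 ± 5.45 CPM against 1.77 ± 0.995 (log2 fold change 2.58, SE 0.50), and Arc at 304 ± 105 against 124 ± 31 (1.29, SE 0.26). Fos (1.68, SE 0.37), Npas4 (1.39, SE 0.42), Egr1 (0.96, SE 0.16), Junb (0.86, SE 0.13), Klf4 (0.76, SE 0.20), Sik1 (0.58, SE 0.18) and Nr4a3 (0.55, SE 0.09) rose with them. Dbp fell (−0.72, SE 0.14) and Per1 rose (0.55, SE 0.15) among clock genes. The glucocorticoid-responsive Plin4 (−0.92, SE 0.27) and Sult1a1 (−0.49, SE 0.15) fell, each adjusted over its list alone, while Irs2 (0.24, SE 0.11) did not pass. Some of these calls, adjusted over the list alone, ended under alternatives that left the fold changes at similar sizes. Klf4, Nr4a3 and Junb did not pass in 1 fit of all 24 libraries (0.75, 0.54 and 0.85, adjusted p = 0.102, 0.102 and 0.063). Nor did Fos, Arc, Sik1 and Egr2 with sample quality weights (1.45, 1.18, 0.49 and 2.32, adjusted p = 0.0908, 0.0538, 0.0538 and 0.0774). The same holds for Fos, Arc and Egr2 with the share of reads in no feature as a covariate (1.60, 1.32 and 2.52, adjusted p = 0.102, 0.073 and 0.0594), and for Fos with no low-count filter (1.70, adjusted p = 0.0539). The immediate early list, not independent evidence, had a median of 0.45 (camera adjusted p = 1.52e-17, and adjusted p = 0.724 with an estimated correlation), with p from 5.04e-24 to 0.739 over its alternatives. The count of 15 became 9 without wild type 2 and 6 without knockout 2. Over all 16119 genes only Cdr1as passed, 646 (4%) had an unadjusted p under 0.05, DESeq2 called 16, and 47 passed without wild type 2.

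Transcripts of tissue around the hippocampus differed strongly between libraries. Choroid plexus and ependymal markers were lower in knockout in 12 of 15 (median −2.34, camera adjusted p = 2.77e-04, and adjusted p = 0.724 with an estimated correlation, with 1.34e-09 to 0.749 over the alternatives), with none past on its own. Aqp1 (−3.71, SE 1.05) and Sostdc1 (−2.34, SE 0.67) had the smallest p. Ttr, the choroid plexus thyroxine carrier, picked after its values were seen, stood at 2170, 4.55 and 1630 CPM in wild type 1 to 3 and at 4.18 to 7.68 CPM in knockout. Meningeal and fibroblast markers were lower in 17 of 17 (median −0.43, adjusted p = 7.43e-05, and 0.724 with an estimated correlation), a call that ended without wild type 3 (−0.12, adjusted p = 0.124) or knockout 3 (−0.18, adjusted p = 0.0535). Nuclear oxidative phosphorylation genes (28 of 28 lower, median −0.28, adjusted p = 5.34e-05), cytosolic ribosomal protein genes (30 of 30 lower, −0.27, adjusted p = 2.77e-04) and replication-dependent histones (17 of 18 lower, −0.46, adjusted p = 5.34e-05) were lower as lists, with no member past. With an estimated correlation their adjusted p was 0.724, 0.728 and 0.724. Without wild type 1 their medians were 0.04, 0.11 and 0.09, where the ribosomal list passed in the other direction (adjusted p = 0.00699). The ribosomal call ended without knockout 2 (−0.17). With the share of reads in no feature as a covariate, the 3 medians were 0.04 (adjusted p = 0.438), 0.09 (adjusted p = 0.00473, in the other direction) and 0.06 (adjusted p = 0.813). With sample quality weights they were −0.02, 0.02 and −0.04 (adjusted p = 0.777, 0.697 and 0.193). Calls that stayed moved to −0.45 and −0.46 for oxidative phosphorylation and ribosomal genes without wild type 3, −0.71 for histones without wild type 2, and −0.26 and −0.94 for meningeal markers without knockout 1 and knockout 2. In wild type 1, 37.0% of reads fell in no feature, against 48.3% to 55.4% in the other 5.

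Other lists also passed camera in the hippocampus. Hippocampus markers (median 0.17, adjusted p = 0.0171), described miR-7 targets and microRNA machinery (0.10, adjusted p = 0.0153) were higher, and neuropeptides (−0.29, adjusted p = 0.00144) and endothelial and pericyte markers (−0.11, adjusted p = 0.0311) were lower. No member of the marker, machinery, neuropeptide or endothelial lists passed on its own: Iyd stood at 0.67 (SE 0.21), Ago4 at 0.27 (SE 0.12), Tac1 at −0.85 (SE 0.28) and Kdr at −0.44 (SE 0.14). With an estimated correlation each adjusted p was 0.724. Leaving out 1 library ended each of these calls. This was wild type 1 (0.01) or knockout 2 (0.08) for machinery and wild type 1 (−0.14) for neuropeptides. It was wild type 3 (0.12), knockout 1 (0.13) or knockout 3 (0.17) for hippocampus markers, and wild type 2 (−0.10), wild type 3 (−0.11), knockout 1 (−0.07) or knockout 3 (−0.13) for endothelial markers. Calls that stayed moved to 0.17 for machinery without wild type 2 and −0.18 for endothelial markers without knockout 2.

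In the olfactory bulb 3 immediate early genes rose against all 15831 genes tested. Fosb stood at 107 ± 21.6 CPM in knockout against 23.6 ± 7.39 (4.51-fold, log2 SE 0.23), Fosl2 at 390 ± 82.3 against 122 ± 21 (log2 fold change 1.68, SE 0.17) and Egr3 at 95.2 ± 18.2 against 31.7 ± 3.37 (1.58, SE 0.16), each with adjusted p = 0.0167 (edgeR). Fosb and Fosl2 encode members of the Fos family of AP-1 proteins, and Egr3 a zinc-finger transcription factor. Of 42 immediate early genes 39 were higher and 24 rose adjusted over the list alone, led by Atf3, a stress-induced transcription factor (17.3 ± 3.7 against 2.1 ± 0.971 CPM, 3.05, SE 0.40), and Nr4a3 (145 ± 32.7 against 26.5 ± 13.1 CPM, 2.45, SE 0.31). Egr2 (1.96, SE 0.53), Fos (1.70, SE 0.40), Junb (1.42, SE 0.47), Arc (1.32, SE 0.31), Egr1 (1.22, SE 0.33) and Sik1 (0.76, SE 0.17) also rose. Klf4 (0.40, SE 0.36) did not pass. Per1 (0.95, SE 0.20) and Irs2 (1.02, SE 0.17) rose adjusted over their own lists alone. The list, not independent evidence, had a median of 0.80 (camera adjusted p = 6.86e-59, and adjusted p = 0.139 with an estimated correlation), with p from 5.08e-136 to 0.139 over its alternatives. Including Cdr1as, 4 genes passed over all genes, 384 (2.4%) had an unadjusted p under 0.05 and DESeq2 called 17. Without wild type 1, wild type 2 or knockout 3 the count was 1, and without wild type 3 it was 8. Without both libraries of low complexity the count of 24 was 16, and Fos (1.22), Arc (1.08), Nr4a3 (2.21), Egr1 (0.87), Junb (1.15), Fosb (2.10) and Sik1 (0.64) no longer passed adjusted over the list alone, in a fit with fewer libraries. With no low-count filter Fos, Arc, Egr2, Egr1 and Junb did not pass it (adjusted p = 0.0749, 0.0776, 0.0907, 0.0979 and 0.139), at nearly the same fold changes (1.71, 1.32, 1.96, 1.23 and 1.43). Nor did Egr1 with sample quality weights (1.07, adjusted p = 0.0623) or the covariate (1.23, adjusted p = 0.0732).

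Genes of the heat shock and unfolded protein response were higher in knockout olfactory bulb in 12 of 18 (median 0.15, camera adjusted p = 1.47e-08, and adjusted p = 0.661 with an estimated correlation, with 4.84e-18 to 0.893 over the alternatives). The co-chaperone gene Dnajb1 stood at 50.2 ± 8.07 CPM against 23.7 ± 4.01 (log2 fold change 1.07, SE 0.19), and Xbp1, a transcription factor of the unfolded protein response, at 95.5 ± 4.42 against 63.9 ± 10.9 (0.58, SE 0.14). Both rose adjusted over the list alone. The list call stayed with each library left out, but its median was −0.01 without wild type 2, 0.32 without wild type 1, and 0.04, 0.25 and 0.07 without knockout 1, 2 and 3. Cytosolic ribosomal protein genes (median 0.06, adjusted p = 4.11e-05), glucocorticoid response genes (0.14, adjusted p = 0.0248, of which Per1 alone rose), presynaptic release genes (0.05, adjusted p = 0.00768), nuclear oxidative phosphorylation genes (0.04, adjusted p = 0.00768) and described miR-7 targets were also higher as lists, with adjusted p of 0.661, 0.661, 0.661, 0.75 and 0.139 with an estimated correlation. Leaving out knockout 1 brought the ribosomal median to 0.00, the presynaptic to −0.04 and the oxidative phosphorylation median to −0.01. Without wild type 2 the last 2 were 0.04 and −0.01 and did not pass. The glucocorticoid call ended without wild type 2 (0.09), knockout 2 (0.15) or knockout 3 (0.08), and without Dusp1 the list median was 0.12 (camera p = 0.0356, and 0.132 with an estimated correlation). With the share of reads in no feature as a covariate, the presynaptic (−0.01, adjusted p = 0.324), oxidative phosphorylation (0.00, adjusted p = 0.8) and ribosomal calls (0.02, adjusted p = 0.26) ended. Calls that stayed moved to 0.03, 0.09 and 0.12 for presynaptic genes (without wild type 1, wild type 3, knockout 2), 0.11 and 0.02 for oxidative phosphorylation genes (knockout 2, knockout 3) and 0.17 for ribosomal genes (knockout 2).

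Averaged over regions, Nr4a3 (ENSMUSG00000028341) rose over all 17600 genes tested, at 120 ± 14.5 CPM in knockout against 41.9 ± 6.49 (log2 fold change 1.52, SE 0.13, adjusted p = 0.00124, limma), the only such gene beside Cdr1as (−11.36, SE 0.16, adjusted p = 1.23e-11). CPM here are means of log values turned back. Of 42 immediate early genes 38 were higher and 28 rose adjusted over the list alone, among them Egr2 (1.89, SE 0.29), Fos (1.88, SE 0.31), Npas4 (1.47, SE 0.37), Arc (1.13, SE 0.15), Junb (1.09, SE 0.19), Egr1 (0.84, SE 0.11), Klf4 (0.79, SE 0.23) and Sik1 (0.77, SE 0.13). Among single regions, 34 immediate early genes passed in at least 1 region, all of them higher there, and 4 in each region (Fos, Nr4a1, Nr4a3, Sik1). Per1 (0.75, SE 0.12) and Irs2 (0.54, SE 0.11) rose, and Dbp (−0.56, SE 0.12), the clock repressor Nr1d2 (−0.31, SE 0.09) and Plin4 (−1.72, SE 0.38) fell, each adjusted over its list alone. The immediate early list, not independent evidence, had a median of 0.73 (camera adjusted p = 7.73e-36, and adjusted p = 0.236 with an estimated correlation), with p from 1.16e-54 to 0.236 over its alternatives. Same-numbered means correlated weakly (r = 0.17 to 0.23), a pairing that the labels do not give. With the number as a block 15 genes passed, 13 of them higher and 9 on the immediate early list, while edgeR on all 24 libraries called 70. That fit takes libraries of different regions as independent. Those with the same number and genotype correlated (median r = 0.12 over 36 pairs, against −0.05 over 72 pairs with different numbers). With genotype and number as a random block (consensus correlation 0.15) 22 genes passed. Without a block 890 genes (5.1%) had an unadjusted p under 0.05, where no change gives a share of 0.05. Without knockout 1 the count of 2 was 4, and without wild type 3 it was 6.

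Choroid plexus and ependymal markers were lower in 16 of 16 in the mean over regions (median −0.83, camera adjusted p = 1.30e-05, and adjusted p = 0.76 with an estimated correlation, with 5.27e-06 to 0.76 over the alternatives). None passed on its own, with Kcnj13 at −1.37 (SE 0.39) and Aqp1 at −1.31 (SE 0.40), and the median was −0.48 without wild type 1. Interferon response genes were lower in 21 of 22 (median −0.28, adjusted p = 0.0103, and 0.899 with an estimated correlation), with none past, and the call ended without knockout 1 (−0.16, adjusted p = 0.0987). Without knockout 3 the median was −0.48. Glucocorticoid response genes were higher as a list (median 0.16, adjusted p = 0.0347, and 0.899 with an estimated correlation). Dusp1 (1.07, SE 0.27) and Per1 passed as higher and Plin4, given above, as lower. The list call ended without knockout 2, knockout 3 or wild type 2 (0.20, 0.09 and 0.07). Without wild type 3 the list median was 0.26, and without Dusp1 it was 0.13 (camera p = 0.0249, and 0.259 with an estimated correlation). In no comparison did a list call hold with an estimated correlation, out of 32 lists tested in the cerebellum, 33 in the cortex, 33 in the hippocampus, 32 in the olfactory bulb and 34 for the mean. Lists not named above did not pass in any comparison, astrocyte, microglia, excitatory neuron, glutamate receptor, insulin signalling and cortex marker lists among them.

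**Figure D2:**
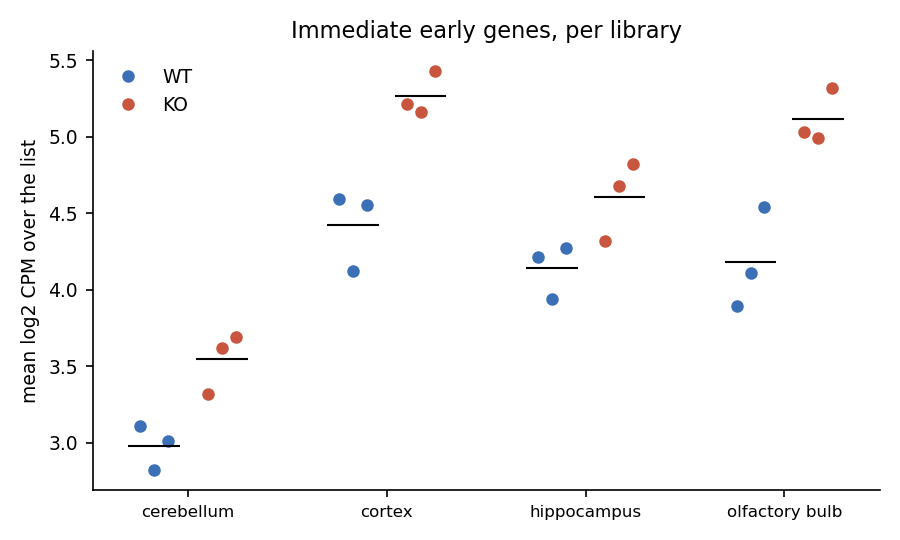
Mean log2 CPM over the immediate early gene list in each library, by region and genotype. Points are libraries and bars are means of 3, and each knockout library lies above each wild-type library of its region (cortex 5.16 to 5.43 against 4.12 to 4.59, hippocampus 4.32 to 4.82 against 3.94 to 4.27).

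**Figure D3:**
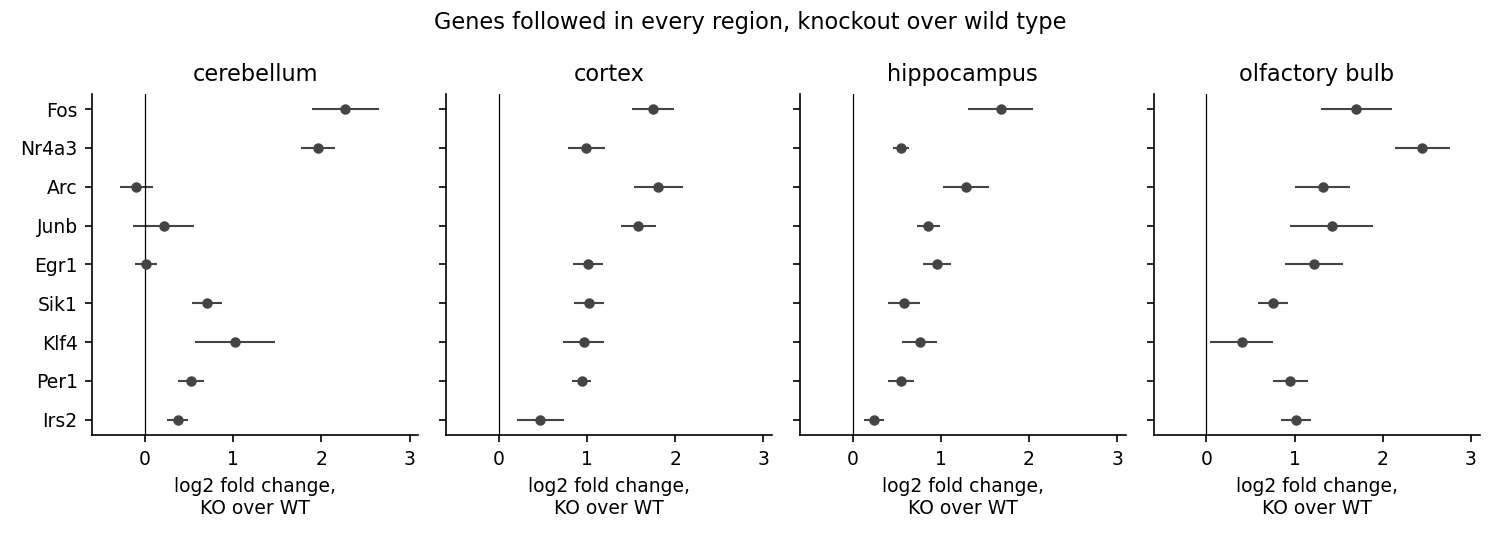
Log2 fold change, knockout over wild type, of 9 genes in each region (points, with 1 SE as lines, edgeR). Fos lies between 1.68 and 2.27 in all regions, while Arc is at −0.10 in the cerebellum and 1.81 in the cortex.

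Effects that differ between regions were sought over 17600 genes. Eomes (ENSMUSG00000032446) was the gene that passed the interaction test (adjusted p = 2.17e-04, edgeR): knockout was higher in the cerebellum (50.9, 53.7 and 67.5 CPM against 28.2, 19.6 and 24), lower in the cortex (0.132, 0.59 and 0.348 against 3.85, 2.77 and 1.87), and not separated from wild type in the hippocampus (0.821 to 1.26 against 0.65 to 1.05) and olfactory bulb (76.9 to 103 against 96.6 to 125). Its log2 fold changes in the fit of all 24 libraries were 1.26, −2.95, 0.08 and −0.27. Against the mean of the other regions, Eomes passed in the cerebellum and cortex, and Sulf1 (ENSMUSG00000016918), an extracellular sulfatase of heparan sulfate, in the hippocampus (adjusted p = 0.0306), where it stood at 25.8, 9.48 and 45.2 CPM in wild type and 4.37, 7.07 and 4.46 in knockout (−2.34). In these libraries the choroid plexus gene Ttr stood at 2170, 4.55 and 1630 CPM in wild type and 7.68, 5.57 and 4.18 in knockout. The 2 libraries highest in Sulf1 are those with high Ttr. Sulf1 missed the interaction test over all regions (adjusted p = 0.153), as did Cdr1as (0.153), Nr4a3 (0.222, with effects of 1.95, 1.01, 0.54 and 2.46 from cerebellum to olfactory bulb) and Frmd7 (0.335, −1.86 in the cortex). No gene passed for the olfactory bulb against the others, where 646 had an unadjusted p under 0.05. The interaction had 261 such genes, and DESeq2 called 15. Both unadjusted counts lie under the share of 0.05 that no change would give. The count of 1 was 2 without cerebellum knockout 1, hippocampus wild type 2, wild type 3 or knockout 3, or olfactory bulb wild type 3. The per-library score of the immediate early list was not shown to differ in its knockout effect between regions (0.56, 0.85, 0.47 and 0.93 log2 units, adjusted p = 0.987, limma), nor that of the olfactory bulb markers (0.18, −0.74, 0.11 and −0.09, adjusted p = 0.203).

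**Figure D4:**
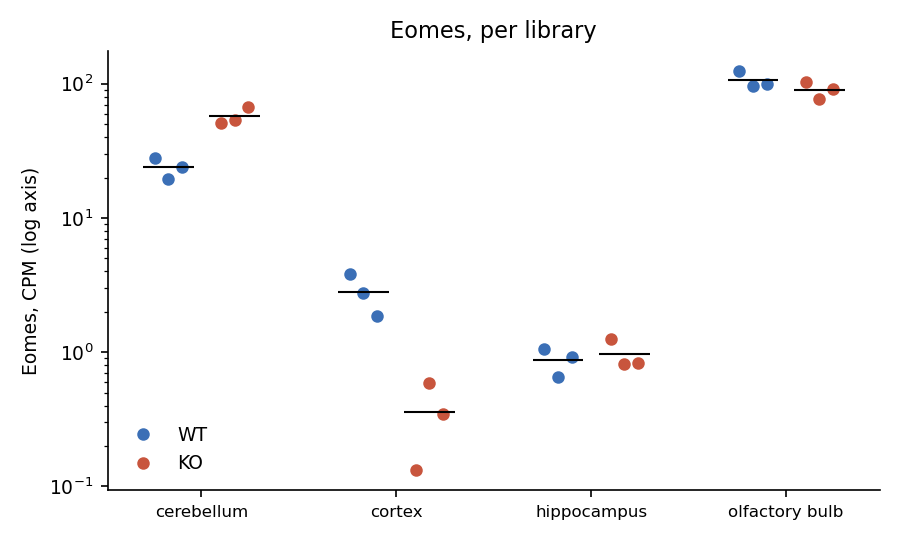
Eomes in each library (CPM, log axis) by region and genotype, with points for libraries and bars for means of 3. Knockout lies above wild type in the cerebellum (50.9 to 67.5 against 19.6 to 28.2) and below it in the cortex (0.132 to 0.59 against 1.87 to 3.85).

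Genes described as miR-7 targets were compared because Cdr1as binds that microRNA. Of 27 measured, 18 were higher in knockout cerebellum, 14 in cortex, 17 in hippocampus, 19 in olfactory bulb and 16 in the mean over regions, with medians of 0.05, 0.03, 0.05, 0.12 and 0.02. Those that rose adjusted over the list alone numbered 2, 3, 3, 3 and 4, and were Fos and Nr4a3 in each comparison, with Klf4 in cortex, hippocampus and mean, and Irs2 in olfactory bulb and mean. The camera adjusted p was 4.81e-04, 0.0386, 0.0171, 1.54e-04 and 9.06e-04, and with an estimated correlation 0.16, 0.556, 0.724, 0.139 and 0.236. This list too is not independent evidence. Fos, Klf4 and Nr4a3 are also on the immediate early list, and without these 3, a step chosen after seeing the data, medians over the other 24 were 0.02, 0.00, 0.03, 0.07 and 0.00 (camera p = 0.039, 0.385, 0.245, 0.0135 and 0.0206, and 0.052 to 0.416 with an estimated correlation). In the cortex the call ended without wild type 2 (0.05), wild type 3 (0.02), knockout 1 (−0.01) or knockout 3 (0.05), and in the hippocampus without wild type 1 (0.03, adjusted p = 0.238), with sample quality weights (0.04, adjusted p = 0.109) and with the share of reads in no feature as a covariate (0.05, adjusted p = 0.181). Where the call stayed, medians without 1 library were 0.03 and 0.08 in the cerebellum (wild type 1, wild type 2), 0.07 in the cortex (wild type 1), 0.03 in the hippocampus (knockout 2), and 0.04, 0.04, 0.05 and 0.01 in the mean (wild type 1, knockout 1, 2 and 3).

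Across the transcriptome, genes with a miR-7 site in the 3′ UTR were not shown to differ from those with control sequences in the planned test. A site was present in 2402 of 19778 genes with a 3′ UTR. Against matched genes without a site the mean log2 fold change differed by −0.002 in the cerebellum (1817 tested site genes, controls 0.009, permutation p = 0.0875), 0.039 in the cortex (controls 0.043, permutation p = 0.712), 0.008 in the hippocampus (permutation p = 0.625), 0.007 in the olfactory bulb (permutation p = 0.988) and 0.011 in the mean (controls 0.017, permutation p = 0.375), with adjusted values of 0.438 to 0.988 over the 5 comparisons. For 8mers alone, permutation p was 0.425 to 0.8 against shuffled 8mers (adjusted 0.8 in each) and 0.0375 in the cerebellum and in the mean, 0.05 in the hippocampus, 0.45 and 0.725 elsewhere against shuffled 7mers (adjusted 0.0833 at the lowest). Without matching on UTR length and expression, 8mers against shuffled 7mers gave 0.0125, the smallest that 79 controls can give, in the cerebellum, hippocampus and mean (shifts −0.014, 0.031 and 0.001, controls 0.004, 0.049 and 0.021, adjusted 0.0208 each). It gave 0.538 and 0.938 elsewhere. Against shuffled 8mers the permutation p without matching was 0.15 to 0.762. For both microRNAs shuffled 7mers are an unlike control for 8mers, because their shifts spread less than those of shuffled 8mers. With matching, sites for miR-671-5p gave permutation p of 0.117, 0.65, 0.617, 0.05 and 0.417 (adjusted 0.25 to 0.65). For their 8mers the lowest was 0.0333 in the olfactory bulb (shift −0.021, adjusted 0.166) against shuffled 8mers. Against shuffled 7mers it was 0.0167 in the olfactory bulb and the mean, the smallest that 59 controls can give (adjusted 0.0417). Without matching these 2 values were 0.0167 and 0.0833, and neither passed once adjusted (0.0832 and 0.139). Camera gave p of 0.0869 to 0.848 for miR-7 site genes, and for miR-671-5p site genes 0.00744 in the hippocampus and 0.0343 in the mean (higher, with 0.152 and 0.242 from an estimated correlation).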

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

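The tests of clock genes, of olfactory bulb transcripts in the cortex and of C230004F18Rik were chosen after the result was seen, as were the fits without the 3 libraries of low complexity and with the share of reads in no feature as a covariate.

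The knockout effect on Eomes differed between regions (interaction adjusted p = 2.17e-04, edgeR), higher in the cerebellum in 3 of 3 knockout libraries and lower in the cortex in 3 of 3. Sulf1 differed in the hippocampus from the other regions (adjusted p = 0.0306): all 3 knockout libraries lay between 4.37 and 7.07 CPM, wild type 2 at 9.48 and the other wild-type libraries at 25.8 and 45.2, while libraries of the other regions held 22.4 to 38.4 CPM. The choroid plexus gene Ttr stood at 2170, 4.55 and 1630 CPM in wild-type hippocampus 1 to 3 and 4.18 to 7.68 in knockout, and choroid plexus and meningeal markers were lower with Sulf1 (medians −2.34 and −0.43). Whether Sulf1 differs within hippocampal tissue was not tested.

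The rise of immediate early genes was weighed against 3 technical explanations. Without the libraries of low complexity the olfactory bulb median was 0.68, against 0.80 with them, and with the share of reads in no feature as a covariate the list medians averaged 0.66 over regions, so both values argue against these as the whole cause. Handling or time of day at dissection could raise the same genes in all regions of an animal. Clock-controlled genes less Arntl, Npas2 and Clock differed by −0.31 between genotypes (knockout −0.17 to 0.15, wild type 0.25 to 0.47; two-sided exact p = 0.1, the smallest that 3 against 3 can give). The size of that difference met the bound written for handling or time of day, a bound set after the result was seen. The labels give no dissection time, so this explanation and an effect of the genotype cannot be told apart.

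Lower markers of other tissues in knockout cortex, Eomes among them, could come from olfactory bulb tissue in the wild-type cortex samples. The 50 genes with the largest excess in wild-type olfactory bulb over wild-type hippocampus, picked from these libraries, had a median of −0.42 (SE 0.12) in the cortex, lower in 41 of 50, and −0.40 at the highest when any 1 wild-type cortex library was left out (−0.35 without knockout 3), which argues against a single library as the cause. Their mean log2 CPM was 2.35, 2.16 and 2.22 in wild type and 1.65, 1.87 and 1.56 in knockout. The median of the 50 genes met neither the bound written for bulb tissue nor the bound written against it, both set after the result was seen. Because dissection and genotype are not separated by the labels, bulb tissue and lower expression in knockout cortex cannot be told apart.

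C230004F18Rik was higher in knockout by 1.20 (SE 0.06) over all regions with the share of reads in no feature as a covariate and by 1.27 (SE 0.24) without it, which argues against that share as the cause. Reads from the altered locus could be counted differently where Cdr1as overlaps it (1.24 in the cerebellum). Both lie on the same strand, so strand does not separate their reads, and this and a real rise cannot be told apart.

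Each set of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The real split and the highest of the others gave 1 and 0 changed genes in the cerebellum, 1 and 0 in the cortex, 1 and 2 in the hippocampus, 4 and 0 in the olfactory bulb and 2 and 2 in the mean over regions, so 2 splits gave as many in the hippocampus and in the mean and 1 (the real one) elsewhere. The real counts include Cdr1as, the gene knocked out, which was the only changed gene in the cerebellum, cortex and hippocampus. In those regions the counts therefore say nothing about other genes. Apart from Cdr1as, 3 genes passed in the olfactory bulb and 1 in the mean. For immediate early genes past the test over the list alone the values were 7 and 0, 29 and 0, 15 and 5, 24 and 0, and 28 and 2, where only the real split reached its count. The study's publication dwells on these genes, so this is not independent evidence. For lists past the camera test they were 7 and 12, 13 and 17, 11 and 13, 7 and 15, and 5 and 17, and 7, 4, 5, 8 and 8 of 10 splits gave as many, so a count of lists does not set the genotype split apart. For the miR-7 site shift 9, 1, 6, 6 and 2 splits gave one as large (0.002 and 0.021, 0.039 and 0.036, 0.008 and 0.019, 0.007 and 0.016, 0.011 and 0.023). Among 40 relabellings of the interaction test 1, the real one, gave as many genes (1 against 0).

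In the cortex and the mean over regions, where same-numbered libraries correlated most, 3 other splits part as many pairs as the real one. A further 6 keep pairs together. The first 3 gave at most 0 changed genes, 0 immediate early genes and 12 lists in the cortex, and 0, 2 and 9 in the mean. The other 6 gave at most 0, 0 and 17 in the cortex and 2, 0 and 17 in the mean.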

How the results depend on the processing

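Fits without the libraries of low complexity and with the share of reads in no feature as a covariate were tests chosen after the result was seen. Values follow the order cerebellum, cortex, hippocampus, olfactory bulb, mean. The cause was not tested for any change below, except that fits with fewer libraries have less power by construction.

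Of the main results over all alternatives, 468 were the same, 81 counts or values moved, 11 lost their call and 5 gained one. Of named genes and lists, 3830 were the same, 217 gained a call, 253 lost one and 10 reversed. The miR-7 site shift stayed short of the threshold with each library left out and under every alternative except 8mers against shuffled 7mers, chosen after the data were seen. With matching these passed only before adjustment, in the cerebellum (−0.005, permutation p = 0.0375) and mean (0.007, permutation p = 0.0375). Without matching they passed in the cerebellum (−0.014, controls 0.004), hippocampus (0.031, controls 0.049) and mean (0.001, controls 0.021), each below its controls. The permutation p was 0.0125 each, and 0.0208 each after adjustment. Shuffled 7mers are an unlike control for 8mers. Their shifts had an SD of 0.006, 0.005 and 0.006, against 0.011, 0.011 and 0.010 for shuffled 8mers. Against shuffled 8mers the permutation p without matching was 0.3, 0.15 and 0.212. Eomes passed the interaction test under every alternative. Immediate early medians stayed above 0 throughout, at 0.35 to 0.57, 0.79 to 0.83, 0.44 to 0.51, 0.68 to 0.85 and 0.65 to 0.77.

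Changed genes numbered 19, 41, 16 and 17 with DESeq2 (interaction 15), 3, 7, 5, 16 and 5 with no low-count filter (interaction 2), 4, 6, 2 and 7 in 1 fit of all 24 libraries and 33, 16, 3 and 13 with sample quality weights. The replicate block gave 30 in the cortex, 6 in the hippocampus, 11 in the olfactory bulb and 15 in the mean, where edgeR on all libraries gave 70 and a random block 22. Numbers do not pair the hippocampus and olfactory bulb libraries. Same-numbered cerebellum libraries correlated only weakly (r = 0.06 to 0.11), and there the block called Cdr1as alone. The covariate gave 62 in the cortex, 2 in the hippocampus and 5 in the mean. Without the libraries of low complexity there were 3 in the cerebellum and 2 in the interaction.

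Immediate early genes past the test over the list alone numbered 13 (DESeq2), 17 (all libraries in 1 fit), 21 (weights) and 17 (without the low-complexity library) in the cerebellum and 9 (all libraries in 1 fit) in the hippocampus. With an estimated correlation their medians of 0.46, 0.81, 0.45, 0.80 and 0.73 had adjusted p of 0.16, 0.348, 0.724, 0.139 and 0.236 (camera), and with fry 0.171, 0.143, 0.739, 0.0756 and 0.12. Lists past the test then numbered 0 in every comparison, except 1 in the mean with fry. They numbered 3 in the cerebellum and 3 in the mean with the stricter filter, 3 in the olfactory bulb in 1 fit, 5 in the hippocampus and 12 in the olfactory bulb with weights, 4, 11 and 11 in cerebellum, olfactory bulb and mean without the low-complexity libraries, and 7 in the hippocampus and 8 in the mean with the covariate.

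Some list calls ended with a quality measure in the fit. Beside the 3 in the olfactory bulb given above, with the covariate these were blood cell markers in the cerebellum (0.43), network loci (−0.21), inhibitory neuron (−0.09) and oligodendrocyte precursor markers (−0.05) in the cortex, and machinery (0.04), neuropeptides (−0.16), described miR-7 targets (0.05) and histones (0.06) in the hippocampus. With sample quality weights they were blood cell (0.15), olfactory bulb (−0.03) and oxidative phosphorylation genes (0.00) in the cerebellum and network loci (−0.13) and ribosomal genes (0.06) in the cortex. In the hippocampus they were machinery (0.06), neuropeptides (−0.17), oxidative phosphorylation genes (−0.02), described miR-7 targets (0.04) and histones (−0.04).

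Further list calls ended under alternatives other than the estimated correlation and fry. Without the low-complexity library these were blood cell markers (0.21), olfactory bulb markers (0.01) and oxidative phosphorylation genes (0.02) in the cerebellum. With the stricter filter they were glucocorticoid (0.14), blood cell (0.64), olfactory bulb (0.28) and oxidative phosphorylation genes (0.07) in the cerebellum and cell cycle genes in the cortex (−0.17). They were also presynaptic genes in the olfactory bulb (0.06) and glucocorticoid (0.16) and interferon genes (−0.22) in the mean. With no low-count filter they were blood cell (0.43), olfactory bulb (0.30) and oxidative phosphorylation genes (0.05) in the cerebellum, precursor markers in the cortex (−0.06) and endothelial markers in the hippocampus (−0.10). In 1 fit of all libraries they were oxidative phosphorylation genes in the cerebellum (0.04), network loci (−0.20) and ribosomal genes (0.13) in the cortex and endothelial markers in the hippocampus (−0.11). In the olfactory bulb that fit ended glucocorticoid (0.15), presynaptic (0.08), oxidative phosphorylation (0.05) and ribosomal calls (0.07). With the replicate block they were glucocorticoid (0.12), blood cell (0.42) and oxidative phosphorylation genes (0.05) in the cerebellum, network loci in the cortex (−0.22) and presynaptic (0.05) and oxidative phosphorylation genes (0.04) in the olfactory bulb. Blood cell markers in the cerebellum missed with upper-quartile factors (0.44). Without small RNA genes, blood cell (0.44) and oxidative phosphorylation genes (0.05) in the cerebellum and precursor markers in the cortex (−0.06) did. Without its low-complexity libraries the olfactory bulb lost the glucocorticoid call (0.09).

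In the hippocampus with the covariate, ribosomal genes passed in the other direction (0.09, adjusted p = 0.00473). Heat shock genes, which were not called without it (−0.20, adjusted p = 0.205), passed as higher (0.15, adjusted p = 5.12e-06). Oxidative phosphorylation genes with the covariate (0.04, adjusted p = 0.438) and ribosomal genes with weights (0.02, adjusted p = 0.697) lost their call at medians near 0. With 1 library left out, medians of heat shock, oxidative phosphorylation and ribosomal genes ran from −0.33 to 0.20, −0.45 to 0.04 and −0.46 to 0.11, the highest without wild type 1. In the cortex, heat shock genes ran from −0.29 to 0.24 (above 0 without wild type 1) and ribosomal genes from −0.03 (without wild type 2) to 0.25, and in the olfactory bulb interferon genes from −0.42 to 0.32 (without wild type 2).

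Leaving out 1 library gave 1 to 3, 1 to 3, 1 to 47, 1 to 8 and 2 to 6 changed genes and 1 to 2 in the interaction. The extremes were 3 without cerebellum knockout 1, 3 without cortex wild type 2, 47 without hippocampus wild type 2, 8 without olfactory bulb wild type 3 and 6 without wild type 3 of the mean (4 without knockout 1), and the count was 1 without olfactory bulb wild type 1, wild type 2 or knockout 3. Immediate early genes past numbered 1 to 17, 21 to 33, 6 to 21, 18 to 26 and 19 to 30 (1 without cerebellum wild type 2, 17 without knockout 1, 9 without hippocampus wild type 2, 6 without knockout 2), and lists 4 to 11, 9 to 15, 8 to 15, 7 to 13 and 5 to 12. Immediate early medians ran from 0.43 to 0.57, 0.67 to 0.91, 0.30 to 0.57, 0.67 to 1.03 and 0.61 to 0.78. Hippocampal Cdr1as ran from −9.99 to −9.45 and missed the threshold without wild type 1 (−9.92, adjusted p = 0.127).

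Depth limits what a count of 0 can exclude: for Cdr1 in knockout cerebellum, levels under 0.0746 CPM. On simulated data 1.5-fold changes were recovered in 14.9%, 7.5%, 35.8%, 17.9% and 73.1% of genes, where depth was not separated from the spread between replicates. Libraries were drawn independently there and many genes changed at once, so recovery in the real libraries can be lower.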

Other observations

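The values of Banp and Ttr, and the tests of Banp, were chosen after the result was seen.

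Banp, which encodes a nuclear protein that binds matrix attachment regions and CpG-rich promoters, was higher in every knockout library than in every wild-type library of its region. It stood at 60.6 to 73.5 CPM against 37.7 to 44 in the cerebellum, 41.6 to 47.3 against 25.1 to 31.3 in the cortex, 49.9 to 59.2 against 32.5 to 41.6 in the hippocampus and 46.6 to 55.7 against 28.5 to 33.6 in the olfactory bulb. In the mean over regions it passed with the replicate block (log2 fold change 0.67, SE 0.09) and missed the threshold in limma without a block (0.67, SE 0.10). Genes without overlap between genotypes made up 9.4% to 13.5% of those tested per comparison, where chance gives 10%.

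Ttr, a marker of choroid plexus, varied between libraries of the same group: 977, 929 and 2.42 CPM in wild-type cerebellum and 205, 536 and 292 in knockout, 211, 58.4 and 2.81 in wild-type cortex and 103, 7.03 and 204 in knockout.

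A hypothesis written before its result was seen held that immediate early genes with a miR-7 site rise more than those without. In the mean over regions, 7 members with a site (Klf4, Ier3, Fos, Nr4a3, Ptgs2, Csrnp1, Egr3) averaged 0.76 and 35 without 0.69 (difference 0.07, two-sided permutation p = 0.739, 100000 permutations). Of relabelled differences 95% lay between −0.42 and 0.43, so with 7 genes the test leaves room for a difference of that size, and the bound set beforehand, a p over the threshold, was wrong because such a p does not exclude one.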
